A study of Mus musculus with 2 samples.

How the data were processed

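Single-cell RNA was measured in CD45+ cells sorted from mouse lungs. Lungs had been perfused, minced and digested with collagenase and DNase at 37°C, a step that itself induces immediate early genes. Whether a library pooled animals is not stated. The kit was the 10x Genomics 3′ kit v3.1, which tags the 3′ end of transcripts, and sequencing was on an Illumina NovaSeq. The deposited tables held raw counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger against mm10 and already limited to called cells. The labels gave version 3.1.3 of Cell Ranger while the header in each count table gave version 3.1.0, and the difference was not resolved. Both tables held 31053 genes, with a lowest total of 500 UMIs per barcode in the control and 501 in the exposed library. Gene positions came from the GENCODE annotation of the same build, matched by identifier for 30934 genes, and 36 symbols occurred more than once.

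Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs, which left 9691 control and 9396 exposed barcodes. The mitochondrial limit removed 621 and 604 barcodes and the gene limit concerned 45 and 73. Doublets (droplets with 2 cells) were scored per library by the share of simulated doublets, 2 per cell, among nearest neighbours, and the expected number (0.8% per 1000 cells) was removed, 751 in the control and 706 in the exposed library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and a shared-neighbour graph of 20 neighbours was clustered by the Leiden method at resolution 1 without batch correction. Mitochondrial, ribosomal, haemoglobin, sex-linked and receptor variable genes were left out of the variable genes. A cluster was named when at least 3 markers of a class stood among its 50 leading genes by fold over all other cells, each seen in at least 10% of its cells, and no other class had more markers among the 10 leading genes. Clusters of cycling cells were kept apart as proliferating, and 1 cluster of 78 control and 42 exposed cells stayed unnamed. Xist had 3 and 1 UMIs in the libraries and the Y-linked Ddx3y 8162 and 7384, so both came from male animals.

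For each of the 11 classes with at least 50 cells in each library, UMIs were summed per library and expressed as CPM with exact Poisson intervals. Log2 ratios of exposed over control carried exact conditional binomial intervals, with 0.5 counts added to each sum, and folds in the text were taken without that addition. Shares carried exact Clopper-Pearson intervals. Depth set the precision: class sums ran from 680943 UMIs in group 2 innate lymphoid cells of the control library to 8922875 UMIs in alveolar macrophages of the exposed library. No p-value was made, since 1 library per group leaves no spread between animals to test against. A gene at 0 counts in 1 library was given a bound against 3 counts.

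Genes were named by size. Among genes with a summed count of at least 50 in a class, the bound of the interval nearest to 0 was ranked, and the 10 highest and 10 lowest were named in classical monocytes, alveolar macrophages and interstitial macrophages, and the 3 highest and 3 lowest elsewhere, where that bound lay beyond 1.5-fold. Left out were mitochondrial, ribosomal, haemoglobin, sex-linked, immunoglobulin and T cell receptor variable genes, and genes below 0.5 times their level outside the class (free RNA). Ccr2 was always named. A list's median log2 ratio was taken over members with a summed count of at least 20, for lists with at least 5 such members, and set beside 10000 random lists of the same size matched on mean expression in 20 bins. Members of each list described were named by the same fixed rule, those with the largest summed count and those with the largest log2 ratio by the nearest bound, 2 to 4 per list. Some members that the rule chose are left out of the text and were not replaced, so a few lists are given with fewer. Up to 2 of each kind are given for lists outside the central 95% of random lists and 1 of each kind for lists inside it, a split set after the medians were seen. The lists covered monocyte chemokines and receptors, aryl hydrocarbon receptor targets, NRF2 and oxidative stress, inflammatory cytokines and NF-kB, type I interferon response, MHC class II, alternative macrophage activation, type 2 lymphocytes, type 1 and type 17 lymphocytes, lysosome and phagocytosis, lipid handling, cell cycle, immediate early and dissociation stress, cytotoxic, T cell activation, naive T cell, neutrophil granules, B cell isotypes, glycolysis and hypoxia, and monocyte to macrophage maturation, with ribosomal, mitochondrial and sex-linked genes as checks.

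The groups, lists, markers, naming rule, filters and 18 alternatives were fixed before the data were examined. The pairing of lists with classes was not, since the 78 pairs described were picked after every median had been seen. Also chosen after the data were seen were the neutrophil-associated genes given in monocytes, the AY036118 and Igkc values given for each class, the genes given after thinning, the monocyte sub-clusters, the clusters left out, the removal of the highest cells and the free-RNA subtraction based on neutrophil genes. Free-RNA estimates above 20% were not used, a limit set after 1 such estimate was seen. The planned free-RNA subtraction by haemoglobin and epithelial genes was first left out and was run only when the text was being checked. The list of mitochondrial transcripts held a pattern error, corrected after the results were seen, which touched no value given here. Alternatives covered the cell filter, doublets, clustering, scaling, count minimum, added counts, weighting of cells, free RNA and thinning. The procedure was tested on simulated data. Of 100 genes made different by a log2 of 1, 58, 71 and 46 passed the naming bound in classical monocytes, alveolar macrophages and interstitial macrophages, and at a log2 of 2 the numbers were 96, 98 and 97. Of 200 doublets made from 2 classes, 126 were removed in the control and 148 in the exposed library, so some doublets remained. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling alone. The 100 µg/m³ dose and the comparison of genotypes named in the series design had no library here.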

Results

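Lung immune cells were compared between a mouse library labelled unexposed control and a library labelled with exposure to diesel exhaust particles (DEP), the fine carbon-rich particles of diesel engine exhaust. The exposed library was labelled as exposed by whole-body inhalation to 500 µg/m³ for 1 hour per day, 5 days per week, over 2 weeks. Cells carrying CD45, the surface protein of white blood cells, had been sorted from digested lungs, and each group held 1 library. The control library held 10312 barcodes with 62047730 unique molecular identifiers (UMIs, tags that count single transcripts) and the exposed library 10000 barcodes with 67030914. After filtering and doublet removal 8940 control and 8690 exposed cells were kept, with medians of 3670 and 4153.5 UMIs per cell. Marker genes named 28 of the 32 clusters of kept cells, 3 were set apart as proliferating by cell cycle genes and 1 stayed unnamed, and each class below means cells like the named type. All levels are given as CPM, the UMIs of a gene per 10⁶ UMIs summed over the class. Square brackets hold 95% intervals, which cover counting error only. A call on a gene list is said to be lost under an alternative where its median there lies inside the range of random lists given with it, or on the other side of 0, and a list inside its range is called outside where its median there leaves it and moves beyond its counting interval. With 1 library per group no test was possible, so every difference below is between 2 libraries, and the exposure and any other difference between the animals, genotype labels, sorts or runs cannot be separated.

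The study's question, as its title states, was how DEP acted on monocyte recruitment, a process that depends on Ccr2, the chemokine receptor that lets classical monocytes leave the bone marrow. Ccr2 transcripts were present at high levels in classical monocytes of both libraries, at 578 CPM [553 to 605] in the control and 775 CPM [755 to 796] in the exposed library. A Ccr2 UMI was seen in 91.7% of 375 control and 97.9% of 580 exposed classical monocytes, at medians of 8779 and 12344.5 UMIs per cell. With cells thinned to 1000 UMIs the intervals overlapped, at 41.0% [36.0 to 46.2] and 49.1% [45.0 to 53.3]. B cells, which should lack the gene, showed a UMI in 0.760% and 0.610% of cells at medians of 3313 and 3659 UMIs, and 2.43 and 1.49 CPM. With the control first, Ccr2 CPM was higher in exposed nonclassical monocytes, 42.4 [34.1 to 52.1] and 82.1 [70.5 to 95.0]. Interstitial macrophages had 139.6 [122 to 159] and 238 [209.9 to 268] CPM. Their thinned shares overlapped (5.1% and 6.6%, 13% and 15%). The CPM was 617 and 530.2 in group 2 innate lymphoid cells, 349 and 308 in NK cells and 80.5 and 77.3 in T cells. It was 296 and 255 in type 2 and 246 and 254 in type 1 dendritic cells. Alveolar macrophages had 33.4 and 23.2 and neutrophils 3.95 and 2.47. The lower value turned in innate lymphoid cells with the stricter filter (log2 ratio 0.12). In alveolar macrophages it turned with that filter (0.041), with doublets kept (0.79) and without 1 mixed cluster (0.29). In T cells the log2 ratio was 0.16 with doublets kept and -0.47 with that filter. Ccr2 (ENSMUSG00000049103) is protein-coding, on chromosome 9 from 124101950 to 124113557 (mm10, plus strand). Both libraries were labelled Ccr2-/-, the control with CD45.1+ and the exposed library with CD45.3+, while the series design names wild-type and knockout mice. Where the disrupted part of the gene lies relative to the 3′ tags is not stated, so these UMIs may come from a disrupted transcript and do not settle the genotype.

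Classical monocytes, the Ly6c2-high cells that enter inflamed tissue from blood, made up a larger share of the exposed library. They were 6.67% [6.16 to 7.22] of the exposed and 4.19% [3.79 to 4.63] of the control library, a ratio of 1.59 [1.39 to 1.82]. Alveolar macrophages, the resident phagocytes of the air spaces, were 6.19% [5.69 to 6.72] of the exposed and 4.96% [4.51 to 5.43] of the control library, a ratio of 1.25 [1.10 to 1.42]. Basophils numbered 22 exposed and 7 control cells, a ratio of 3.23 [1.33 to 8.96], and proliferating cells 71 and 107, a ratio of 0.683 [0.498 to 0.930]. The proliferating ratio was 0.789 [0.586 to 1.06] with the stricter filter, 0.942 [0.717 to 1.24] with doublets kept and 0.839 [0.590 to 1.19] with each library clustered alone. NK cells had a ratio of 0.899 [0.809 to 0.999], which was 0.910 [0.816 to 1.01] at Leiden resolution 1.6, 0.944 [0.848 to 1.05] with each library clustered alone and 0.940 [0.846 to 1.04] with the compartment as denominator. The ratio intervals of the other named classes included 1 (0.981 for neutrophils, 0.940 for B cells, 1.01 for T cells, 0.877 for interstitial macrophages, 0.916 for nonclassical monocytes). The intervals of 4 of these classes excluded 1 under some alternatives. For B cells they lay above 1 with the stricter filter, 1.16 [1.08 to 1.25], and below 1 with no cell filter (0.900), with doublets kept (0.892) and at Leiden resolutions 0.6 and 1.6 (0.929 and 0.925). They were 1.15 [1.06 to 1.25] with each library clustered alone for T cells, 0.923 [0.874 to 0.974] with the stricter filter and 0.927 [0.878 to 0.978] with the compartment as denominator for neutrophils and 0.7498 [0.572 to 0.981] with the stricter filter for interstitial macrophages. For dendritic cells the ratios were 1.04 for type 1, 0.914 for type 2, 1.27 for mature and 1.11 for plasmacytoid cells, and they were 0.831 for gamma-delta T cells and 0.954 for group 2 innate lymphoid cells. When the monocytes were clustered on their own, a step added after their genes had been seen, 2 sub-clusters held 331 exposed and 5 control cells, and without them the ratio was 0.719, the other direction. Those cells were chosen by their library, so leaving them out must lower the ratio and does not show what it rests on. The basophil ratio was 1.12 [0.609 to 2.06] with no cell filter.

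**Figure D1:**
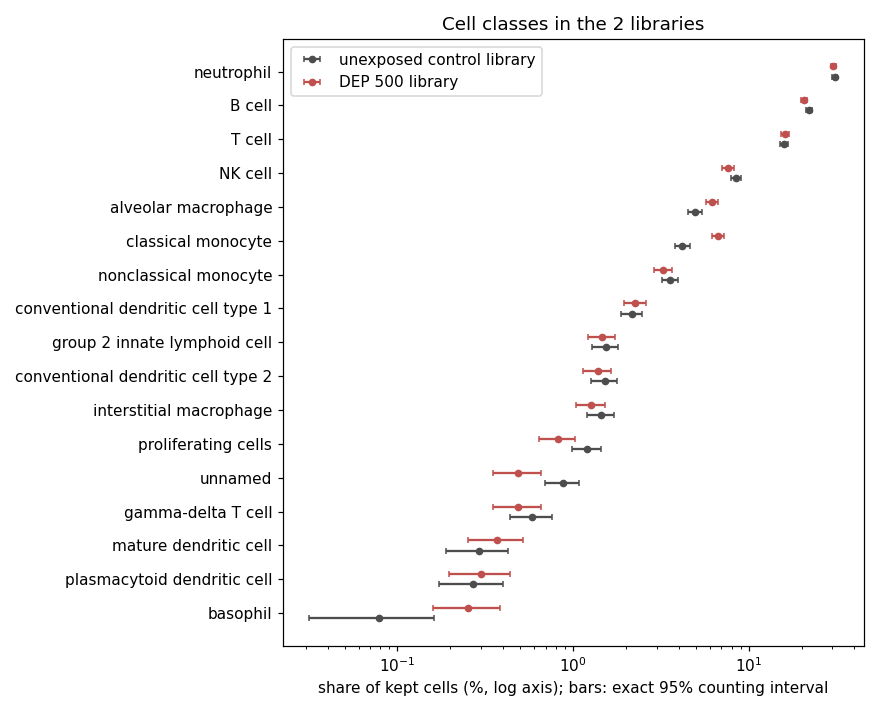
Share of kept cells (percent, log axis) of each class in the unexposed control (grey) and DEP 500 (red) library, with exact 95% counting intervals as bars. The classical monocyte intervals, 3.79 to 4.63% in the control and 6.16 to 7.22% in the exposed library, lie apart.

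Lrg1, Saa3, Prtn3, Vcan, Cd38 and Igfbp6 were among the 10 genes named as higher in classical monocytes of the exposed library (CPM values here and below give the exposed library first). Lrg1, a secreted glycoprotein of the acute-phase response, was at 129 CPM [121 to 138] in the exposed against 0.892 CPM [0.184 to 2.61] in the control library, a 145-fold [49.4 to 703] difference on 952 and 3 UMIs. Saa3, an acute-phase serum amyloid protein, was 16.5-fold [12.6 to 22.0] higher (264 against 16.1 CPM). Prtn3, a granule protease of early myeloid cells, was 12.0-fold [7.82 to 19.2] higher (78.2 against 6.54 CPM), and Vcan, a matrix proteoglycan of classical monocytes, 3.97-fold [3.46 to 4.58] higher (267 against 67.2 CPM). Cd38, an ectoenzyme that uses NAD, was 22.2-fold [10.1 to 61.0] higher and Igfbp6, a binding protein of insulin-like growth factors, 23.5-fold [9.95 to 73.1] higher. With doublets kept the Cd38 log2 ratio was 2.97, against 4.36 without them. The remaining genes named as higher, as log2 ratios, were Fabp7 at 4.15 [2.19 to 10.05], F11r at 2.71 [2.02 to 3.58], Lsmem1 at 3.56 [1.96 to 6.94] and Ube2c at 2.88 [1.73 to 4.66]. After thinning to 1000 UMIs, a Lrg1 UMI was seen in 10.5% of exposed and 0 of 373 control monocytes (3 of 375 before thinning). All thinned cells had one in 9.31% (exposed) and 4.74% (control), and B cells, taken as background, in 0.111% and 0 of 1957. F11r lay at 1.90% and 1.07%, not apart at this depth. Lrg1 is ENSMUSG00000037095 on chromosome 17 from 56119678 to 56122001, Saa3 is ENSMUSG00000040026 on chromosome 7 from 46711998 to 46715700 and Prtn3 is ENSMUSG00000057729 on chromosome 10 from 79874476 to 79883174, all protein-coding.

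Genes named as lower in exposed monocytes included Cd209a, a lectin of monocyte-derived dendritic cells, at 10.0 against 61.8 CPM (6.16-fold [4.71 to 8.15] lower in the exposed library), and Ifit1, an antiviral interferon-induced gene, 4.01-fold [2.71 to 6.02] lower. As log2 ratios the others were Lyz1 (-2.29), Upb1 (-2.75), Flt1 (-1.70), Slamf7 (-1.76), Itga1 (-1.57), Gm1673 (-1.35) and Tmcc3 (-1.36). Retnla, a secreted protein of alternatively activated macrophages, had 705 control and 7 exposed UMIs, but 1 control cell held 86.7% of the control UMIs. Neutrophil-associated genes picked after their values were seen were also higher in exposed monocytes. They were S100a8 (558 against 102 CPM), Lcn2 (99.0 against 4.76 CPM), Wfdc21 (117 against 3.27 CPM) and Chil3 (2118 against 1120.1 CPM), with S100a9 (1.53), Hp (0.99), Mmp8 (0.91) and Retnlg (0.43) as log2 ratios, while Cd177 was lower (-0.80). The list of neutrophil granule and maturation genes fixed in advance, given in addition to the pairs described, lay inside the random range in these cells, with a median of 0.21 (6 of 9 higher) against -0.30 to 0.26. With doublets kept the log2 ratios were 0.44 for S100a8, -0.16 for S100a9 and -1.36 for Retnlg. S100a9 was also lower with the added free-RNA subtraction (-2.25), as was Retnlg (-4.99), and Retnlg with each cell weighing the same (-0.31) and with the stricter filter (-0.24), so neither is a stable difference. Without the sub-clusters found almost only in the exposed library, S100a8 had a log2 ratio of -0.62 and S100a9 of -0.19, and S100a9 of -0.062 without the larger of them alone. Lrg1 stayed higher outside them, at 33.5 against 0.904 CPM.

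**Figure D2:**
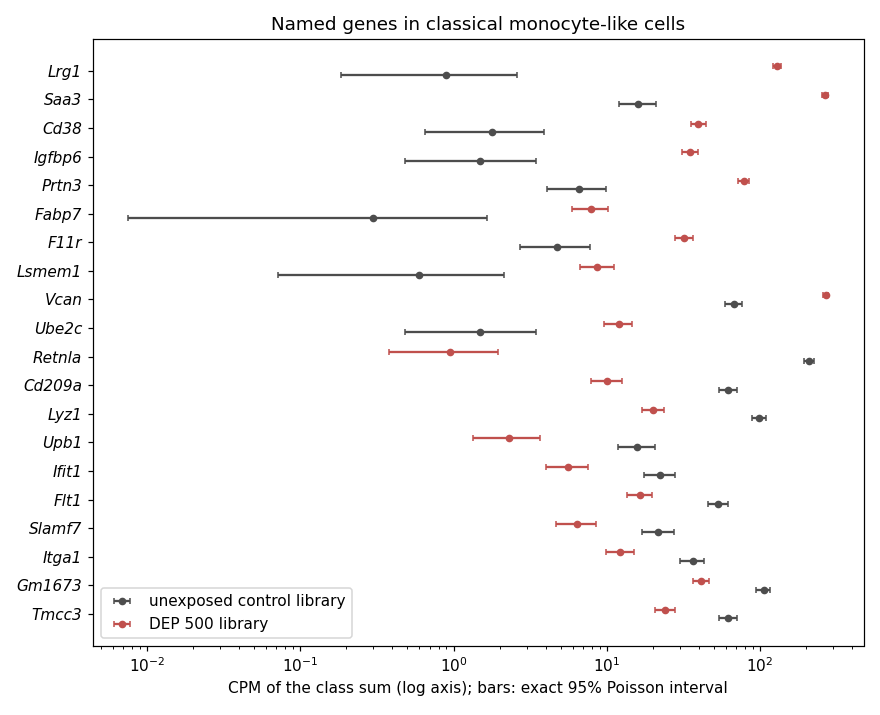
CPM of the class sum (log axis) of the 20 genes named in classical monocyte-like cells in the unexposed control (grey) and DEP 500 (red) library, with exact 95% Poisson intervals as bars. Lrg1 lies at 0.892 CPM in the control and 129 CPM in the exposed library, and Tmcc3 at 61.8 and 24.1 CPM.

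Among the gene lists, inflammatory cytokine and NF-kB genes were higher in exposed monocytes and interferon, MHC class II and chemokine genes lower (values of list members here and below are log2 ratios unless CPM is stated). Of the inflammatory list 10 of 15 counted members were higher, with a median log2 ratio of 0.31 against -0.17 to 0.17 for the central 95% of random lists. Il1b (the interleukin 1 beta gene) was at 1.01 [0.99 to 1.04], Nfkbia at 0.51 [0.47 to 0.54] and Cxcl1 (a neutrophil attractant) at 1.31 [1.12 to 1.50]. Of the interferon list 17 of 18 were lower, with a median of -0.39 against -0.19 to 0.16, a call lost with each cell weighing the same (-0.18). Ifitm3 (an antiviral membrane protein gene) was at -0.091 [-0.12 to -0.067], Ifi27l2a at -0.097 [-0.13 to -0.059], Ifit1 at -1.996 [-2.59 to -1.44] and Mx1 at -1.33 [-1.72 to -0.94]. MHC class II genes, which present peptides to CD4 T cells, had 11 of 13 lower and a median of -0.43 against -0.21 to 0.20. Cd74 (the invariant chain gene) was at -0.50 [-0.54 to -0.47], Ctss (a protease gene) at 0.093 [0.053 to 0.13], H2-DMb2 at -1.94 [-2.80 to -1.14] and H2-Aa at -0.59 [-0.66 to -0.53]. Monocyte chemokines and receptors had 8 of 13 lower and a median of -0.47 against -0.20 to 0.20, a call lost at a minimum of 1 count (-0.099). Ccl6 was at -0.49 [-0.55 to -0.44], Ccr2 at 0.42 [0.35 to 0.50] and Ccl5 at -1.21 [-1.35 to -1.07]. NRF2 and oxidative stress genes had 12 of 15 higher and a median of 0.21 against -0.19 to 0.18. Fth1 (the ferritin heavy chain gene) was at 0.32 [0.30 to 0.34], Ftl1 at 0.21 [0.18 to 0.24], Gsr at 0.51 [0.43 to 0.59] and Gclm at 0.88 [0.37 to 1.46]. Glycolysis genes had 9 of 11 higher and a median of 0.32 against -0.22 to 0.23. Pkm was at 0.32 [0.24 to 0.40], Aldoa at 0.49 [0.39 to 0.60], Vegfa at -0.87 [-1.04 to -0.69] and Ldha at 0.54 [0.40 to 0.68]. Genes of monocyte to macrophage maturation had 8 of 11 lower and a median of -0.47 against -0.30 to 0.26, a call lost without the highest cells (-0.22), with doublets kept (-0.27) and with the stricter filter (-0.27). Apoe was at -0.41 [-0.45 to -0.37], Ly6c2 at -0.75 [-0.80 to -0.70] and Vcan at 1.99 [1.79 to 2.20]. Alternative activation genes had 5 of 7 lower and a median of -1.50 against -0.39 to 0.32, a call lost at a minimum of 100 counts (-0.20). Chil3 was at 0.92 [0.87 to 0.97], Retnla at -7.69 [-9.11 to -6.74] (86.7% of the UMIs of the higher library in 1 cell) and Mrc1 (the mannose receptor gene) at -1.50 [-2.02 to -0.99]. Immediate early genes had 16 of 18 lower and a median of -0.21 against -0.11 to 0.16. Junb was at -0.025 [-0.070 to 0.020], Jund at -0.21 [-0.27 to -0.16], Ier3 at 1.34 [1.21 to 1.47] and Dusp1 at -0.37 [-0.43 to -0.32]. Lists inside the random range were lysosome 0.14 (9 of 14 higher, Psap -0.31, Axl -1.44), lipid handling 0.13 (7 of 10 higher, Apoe -0.41, Trem2 0.85) and cell cycle -0.16 (4 of 9 higher, Hmgb2 0.12, Ube2c 2.88).

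Without the cells found almost only in the exposed library, which were chosen by library and so do not show what a median rests on, the inflammatory median was -0.15, the NRF2 median -0.25 and the immediate early median 0.35, each in the other direction. The interferon median was -0.00545, the chemokine median -0.16 and the glycolysis median 0.14, inside their ranges. The MHC class II median was -0.63 without both of those sub-clusters and 0.00611 without the larger of them alone, where the NRF2 median was 0.14, the immediate early median -0.00464 and the maturation median -0.29, inside their ranges.

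Alveolar macrophages of the exposed library had lower MHC class II and interferon transcripts. Of the MHC class II list 11 of 13 members were lower, with a median of -1.02 against -0.15 to 0.095. Ctss was at 0.00523 [-0.022 to 0.032], Cd74 at -1.11 [-1.15 to -1.07], H2-Eb1 at -1.20 [-1.28 to -1.12] and H2-Aa at -1.16 [-1.22 to -1.09]. Of the interferon list 12 of 14 were lower, with a median of -0.63 against -0.22 to 0.094, a call lost with doublets kept (0.42), with the stricter filter (-0.10) and without the mixed cluster (-0.15). Ifitm3 was at -1.24 [-1.36 to -1.12], Ifi27l2a at -0.71 [-0.85 to -0.57] and Cxcl10 at -0.99 [-1.14 to -0.84]. These medians moved with 1 mixed cluster of 46 control and 22 exposed cells with H2-Ab1 at 2250.5 and 1244 CPM, against 326 and 227 CPM in the other cluster. The MHC class II median was -0.44 without it and -0.51 with doublets kept, and the interferon median was -0.35 at a minimum of 1 count. Lists of other cell types, given in addition to the pairs described, lay below the random lists in these cells too, with medians of -1.76 for naive T cell, -0.96 for B cell isotype and -0.73 for cytotoxic genes.

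Most counted chemokine and inflammatory genes were also lower in exposed alveolar macrophages. Monocyte chemokines and receptors had 10 of 14 lower and a median of -0.25 against -0.18 to 0.079, a call lost with doublets kept (-0.098) and without the mixed cluster (-0.066). Ccl6 was at 0.22 [0.20 to 0.24], Ccr1 at -0.13 [-0.22 to -0.027], Ccl5 at -1.03 [-1.20 to -0.86] and Ccl4 at -0.9998 [-1.19 to -0.82]. Inflammatory genes had 11 of 15 lower and a median of -0.18 against -0.11 to 0.070, a call lost with doublets kept (0.043). Cxcl2 was at 0.079 [0.048 to 0.11], Nfkbia at -0.14 [-0.17 to -0.11], Ptgs2 at -1.14 [-1.43 to -0.87] and Il6 at -1.02 [-1.32 to -0.72]. Cell cycle genes had 12 of 14 lower and a median of -0.36 against -0.26 to 0.14, a call lost at a minimum of 100 counts (-0.13), with each cell weighing the same (-0.18), with the stricter filter (-0.17) and without the mixed cluster (-0.15). Tubb5 was at -0.095 [-0.17 to -0.022], Hmgb2 at -0.16 [-0.26 to -0.054], Cdk1 at -1.14 [-1.94 to -0.42] and Mki67 at -0.88 [-1.45 to -0.35]. Genes named as higher were AY036118, a long noncoding transcript, 2.04-fold [1.93 to 2.17] higher, the heat shock genes Hspa1a and Hspa1b, 1.83-fold [1.69 to 1.99] and 1.79-fold [1.65 to 1.93] higher with 36.6% and 31.2% of the exposed UMIs in 1 cell and log2 ratios of 0.31 and 0.39 without it, and Slx4, a nuclease scaffold of DNA repair, 2.69-fold [1.51 to 5.004] higher. Genes named as lower were Mmp12, the macrophage elastase, 2.91-fold [2.12 to 4.04] lower, and, as log2 ratios, Cxcl10 (-0.99), Il6 (-1.02), Ece1 (-1.15), Phlpp1 (-1.23), Tgfb2 (-1.18) and Inhba (-1.29). The Cxcl10 log2 ratio was -0.49 with doublets kept and -0.54 with the stricter filter. Retnla and Cd209a were also named, at -6.41 and -2.58, with Retnla UMIs in 8 control cells. Without the mixed cluster, where Retnla was at 435 CPM in the control library, their log2 ratios were -0.70 and -0.80. Inside the random range lay NRF2 -0.031 (5 of 15 higher, Fth1 0.16, Slc7a11 -0.84), alternative activation -0.15 (2 of 9 higher, Chil3 0.081, Retnla -6.41; outside without the highest cells at -0.55 and with the stricter filter at -0.81), lysosome 0.047 (10 of 16 higher, Ctsd 0.054, Cd63 0.60; outside with the stricter filter at 0.094), lipid handling 0.068 (6 of 11 higher, Lpl 0.068, Fabp5 0.49; outside with the stricter filter at 0.10), immediate early 0.016 (9 of 18 higher, Junb -0.094, Hspa1a 0.87) and glycolysis -0.12 (3 of 11 higher, Aldoa -0.026, Vegfa -1.07).

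Interstitial macrophages, the C1q-producing macrophages of the lung tissue, had lower chemokine and inflammatory transcripts in the exposed library. Monocyte chemokines and receptors had 10 of 14 lower and a median of -0.32 against -0.12 to 0.11. Ccl4 was at -0.94 [-1.01 to -0.86], Ccl2 at -0.54 [-0.63 to -0.45] and Ccl5 at -1.83 [-2.24 to -1.45]. Inflammatory genes had 10 of 16 lower and a median of -0.22 against -0.13 to 0.11, a call lost at a minimum of 100 counts (-0.089). Cxcl2 was at -0.46 [-0.50 to -0.42], Il1b at 0.35 [0.28 to 0.42], Il6 at -3.34 [-4.12 to -2.70] and Cxcl3 at -1.93 [-2.63 to -1.33]. Maturation genes had 8 of 11 higher and a median of 0.24 against -0.18 to 0.16, a call lost without the highest cells (0.10), with doublets kept (0.13) and with the stricter filter (0.056). Apoe was at 0.40 [0.38 to 0.43], C1qa (a complement gene) at 0.32 [0.27 to 0.36] and C1qb at 0.37 [0.33 to 0.42]. Alternative activation genes had 7 of 9 lower and a median of -0.29 against -0.19 to 0.16. Mrc1 was at -0.18 [-0.29 to -0.082], Retnla at -2.44 [-2.62 to -2.26] (79.5% of the UMIs of the higher library in 1 cell) and Ccl17 at -2.60 [-4.06 to -1.56] (95.2% of the UMIs of the higher library in 1 cell). Cell cycle genes had 9 of 14 lower and a median of -0.80 against -0.29 to 0.22, a call lost at a minimum of 100 counts (0.029), with each cell weighing the same (0.34) and without the highest cells (0.11). Tubb5 was at -0.23 [-0.43 to -0.037], Hmgb2 at 0.029 [-0.19 to 0.25], Ube2c at -1.77 [-2.71 to -0.99] (94.5% of the UMIs of the higher library in 1 cell) and Ccnb2 at -2.23 [-4.35 to -0.87] (79.3% of the UMIs of the higher library in 1 cell). Inside the random range lay NRF2 0.12 (10 of 15 higher, Fth1 0.15, Hmox1 1.06; outside with doublets kept at 0.17), interferon -0.057 (8 of 16 higher, Ifi27l2a 0.71, Rsad2 -4.86; outside at a minimum of 100 counts at -0.26), MHC class II 0.12 (10 of 13 higher, Cd74 0.21, H2-Eb1 0.26; outside with the stricter filter at 0.25), lysosome -0.012 (7 of 16 higher, Ctsb -0.18, Psap -0.24), lipid handling 0.081 (6 of 11 higher, Apoe 0.40, Fabp5 -1.05; outside with doublets kept at 0.39 and with the stricter filter at -0.24), immediate early -0.044 (7 of 18 higher, Junb 0.11, Egr1 -0.58; outside with each cell weighing the same at -0.20) and glycolysis 0.096 (6 of 11 higher, Aldoa -0.075, Hk2 -1.17).

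Single genes of the interstitial macrophages rested on few cells, 129 in the control and 110 in the exposed library. Named as higher were AY036118 (3.34-fold [2.84 to 3.93]), Plau, the urokinase gene (3.25-fold [1.83 to 6.01]), Ctla2a (2.69-fold [1.69 to 4.37]), Slamf7 (1.95-fold [1.57 to 2.42]), Pmepa1 (1.75-fold [1.52 to 2.03]) and the interferon-induced Ifi27l2a (1.63-fold [1.51 to 1.77]). With doublets kept Ctla2a and Ifi27l2a had log2 ratios of 0.58 and 0.55, and with each cell weighing the same Slamf7 had 0.58. Hmox1, the heme oxygenase gene, was 2.09-fold [1.81 to 2.40] higher, but 1 exposed cell held 61.8% of its UMIs and the log2 ratio was -0.20 without the highest cells. Named as lower were Serpinb2 with 466 control UMIs in 4 cells and 0 exposed UMIs, at least 111-fold lower against a floor of 3 counts, and Prg4 with 361 and 0 UMIs, at least 86.3-fold lower. Saa3 had 317 control UMIs in 5 cells and 1 exposed UMI, and Alox15 and Fabp3 had 94 and 76 control UMIs in 3 and 5 cells and 0 exposed UMIs. The bounds of Serpinb2 and Prg4 did not hold with doublets kept or with the stricter filter. With doublets kept the log2 ratios of Serpinb2, Prg4, Saa3 and Alox15 were -2.38, -1.53, -0.58 and -0.37, and with the stricter filter -2.60, -2.19, -0.72 and -0.92. The muscle genes Actc1, Sln, Myl7, Myl4 and Mb had 171, 115, 263, 193 and 99 control UMIs, of which 99.4%, 99.1%, 99.2%, 100% and 100% were in 1 cell. Without the highest cells the Myl7, Myl4 and Mb log2 ratios were -0.26, 2.06 and 0.48.

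Neutrophils of the exposed library had higher interferon-induced transcripts. Of the interferon list 16 of 17 members were higher, with a median of 0.68 against -0.23 to 0.068. Ifitm3 was at 0.50 [0.46 to 0.55], Isg15 (a ubiquitin-like protein gene) at 0.76 [0.71 to 0.80], Oas1a at 1.99 [1.27 to 2.85] and Oasl2 at 1.09 [0.97 to 1.22]. The median stayed above 0 under every alternative run. Of the neutrophils 376 of 2635 exposed and 209 of 2763 control cells lay in 1 cluster led by interferon genes such as Rsad2, Slfn4 and Ifit1, and the median without that cluster was not measured. Other lists lay below the random lists in the same cells, at -1.53 for naive T cell, -1.16 for B cell isotype, -0.69 for cytotoxic, -0.52 for MHC class II and -0.24 for ribosomal protein genes. Isg15 was at 1322 CPM [1298 to 1348] in the exposed against 783 CPM [763 to 803] in the control library. It was seen in 50.2% [48.3 to 52.2] of exposed and 35.2% [33.4 to 37.0] of control neutrophils thinned to 1000 UMIs, and in 1.22% and 0.818% of B cells. Granule and maturation genes had 8 of 12 higher and a median of 0.24 against -0.22 to 0.087. Lcn2 was at 0.62 [0.58 to 0.66], Mmp9 at -0.12 [-0.16 to -0.075], Camp (a secondary granule gene) at 2.22 [2.09 to 2.36] and Ngp at 1.99 [1.89 to 2.08]. Camp was 4.67-fold [4.26 to 5.13] and Ngp 3.96-fold [3.72 to 4.23] higher. Camp UMIs were in 8 control and 36 exposed cells, so this difference rested on a small part of the class. Olfm4, a granule protein of a neutrophil subset, was 5.32-fold [3.83 to 7.53] higher, and Pdpn, Snhg9 and Spp1 (osteopontin) were 5.87-fold [2.73 to 14.4], 3.12-fold [2.25 to 4.39] and 2.001-fold [1.76 to 2.27] lower. Chemokines and receptors had 10 of 14 lower and a median of -0.33 against -0.30 to 0.10, a call lost with the added free-RNA subtraction (-0.083) and with the planned free-RNA subtraction (-0.22). Ccl6 was at 0.019 [-0.00804 to 0.045], Ccr1 at -0.34 [-0.38 to -0.30], Ccl4 at -0.57 [-0.64 to -0.51] and Ccl5 at -0.65 [-0.90 to -0.40]. Inside the random range lay NRF2 -0.028 (5 of 15 higher, Fth1 -0.028, Mt1 -1.19), inflammatory 0.015 (7 of 14 higher, Il1b 0.081, Nfkbia 0.49), immediate early -0.035 (8 of 18 higher, Dusp1 -0.37, Egr1 -0.47) and glycolysis 0.039 (6 of 11 higher, Pkm 0.039, Hk2 -0.86) genes.

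**Figure D3:**
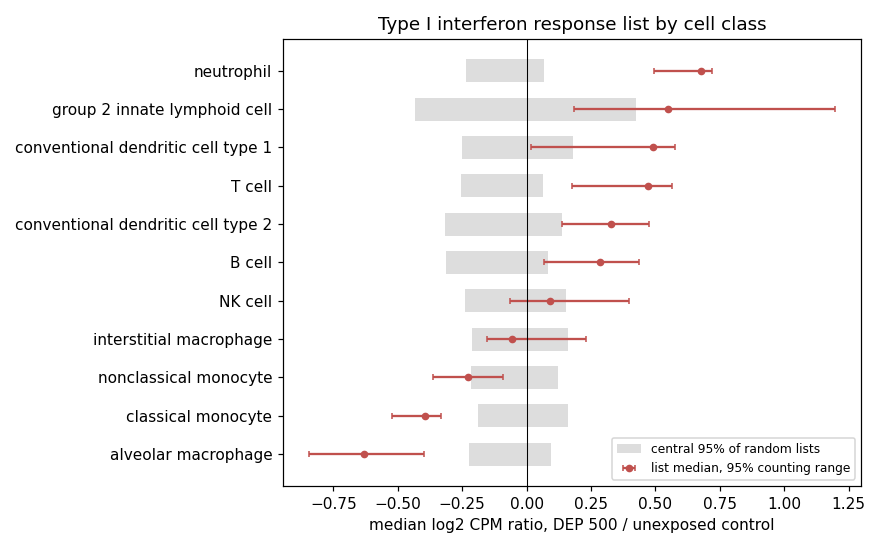
Median log2 CPM ratio (DEP 500 over unexposed control) of the type I interferon list per cell class, with bars for the 95% counting range of the median and grey bands for the central 95% of random lists. Neutrophils lie at 0.68 and alveolar macrophages at -0.63, and with doublets kept the direction turned in alveolar macrophages (0.42), group 2 innate lymphoid cells (-0.54) and nonclassical monocytes (0.13).

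Nonclassical monocytes, which patrol the vessel wall, shared the higher Lrg1 of the classical monocytes, at 91.2 against 27.8 CPM (3.28-fold [2.44 to 4.46]). Wfdc17, a secreted protein of activated macrophages, was 2.65-fold [2.35 to 2.999] higher and AY036118 2.46-fold [2.13 to 2.85] higher. Lyz1 was 31.7-fold [10.5 to 157] lower with 48.9% of the control UMIs in 1 cell, Spp1 2.89-fold [1.87 to 4.58] lower and Il1r2, a decoy receptor for interleukin 1, 2.15-fold [2.01 to 2.30] lower. Without 1 mixed cluster the log2 ratios were 4.05 for Lrg1, 2.02 for Wfdc17, -3.80 for Spp1 and 1.56 for Il1r2, the last in the other direction. It held 127 control and 101 exposed cells and carried neutrophil transcripts, with S100a8 at 22757 and 23791 CPM. Interferon genes had 12 of 16 lower and a median of -0.23 against -0.22 to 0.12, a call lost at a minimum of 1 count (-0.19), with doublets kept (0.13) and with the stricter filter (0.010). Ifitm3 was at 0.097 [0.050 to 0.14], Ifi27l2a at 0.35 [0.27 to 0.44] and Mx1 at -1.94 [-3.33 to -0.85]. Cell cycle genes had 7 of 7 lower and a median of -0.41 against -0.39 to 0.29, a call lost at a minimum of 1 count (-0.11), with 5 counts added (-0.31), with each cell weighing the same (-0.16) and without the highest cells (-0.28). Hmgb2 was at -0.16 [-0.28 to -0.035], Tubb5 at -0.11 [-0.37 to 0.15], Stmn1 at -1.67 [-2.84 to -0.71] (51.4% of the UMIs of the higher library in 1 cell) and Top2a at -1.07 [-2.18 to -0.098]. Inside the random range lay chemokines -0.00885 (6 of 12 higher, Ccl6 -0.24, Ccl2 2.80), NRF2 0.017 (8 of 14 higher, Fth1 -0.00779, Hmox1 1.17; outside without the mixed cluster at 0.29), inflammatory 0.073 (10 of 15 higher, Il1b 0.48, Il6 1.56; outside with doublets kept at 0.32 and without the mixed cluster at 0.25), MHC class II 0.019 (6 of 10 higher, Cd74 0.026, H2-Eb1 0.32; outside with doublets kept at -0.23), lysosome -0.17 (5 of 13 higher, Psap -0.23, Cd63 -0.90), lipid handling -0.19 (3 of 10 higher, Apoe -0.11, Fabp5 0.93; outside with doublets kept at -0.37), immediate early -0.14 (8 of 18 higher, Junb 0.015, Atf3 -0.55) and glycolysis 0.088 (7 of 11 higher, Pkm 0.069, Vegfa -0.89; outside with doublets kept at 0.18) genes.

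Type 2 conventional dendritic cells, which present antigen to CD4 T cells, had higher inflammatory, interferon and MHC class II transcripts in the exposed library. Inflammatory genes had 11 of 14 higher and a median of 0.26 against -0.19 to 0.15. Il1b was at 0.77 [0.72 to 0.83], Nfkbia at 0.21 [0.15 to 0.28] and Ptgs2 at 0.93 [0.77 to 1.09]. Interferon genes had 11 of 17 higher and a median of 0.33 against -0.32 to 0.14. Ifitm3 was at 0.46 [0.39 to 0.53], Ifi27l2a at 0.29 [0.18 to 0.41] and Isg15 at 0.84 [0.53 to 1.16]. MHC class II genes had 9 of 13 higher and a median of 0.18 against -0.12 to 0.17. Cd74 was at 0.21 [0.19 to 0.23], H2-Aa at 0.18 [0.15 to 0.21], H2-DMb1 at 0.37 [0.27 to 0.47] and H2-Eb1 at 0.28 [0.25 to 0.31]. Immediate early genes had 14 of 18 lower and a median of -0.19 against -0.090 to 0.15. Junb was at -0.025 [-0.096 to 0.046], Jund at -0.032 [-0.11 to 0.049], Klf2 at -0.94 [-1.18 to -0.70] and Fos at -0.65 [-0.80 to -0.50]. Ifitm1, an interferon-induced membrane protein, was 8.69-fold [7.27 to 10.5] higher, Serpinb1a 4.54-fold [2.55 to 8.62] and Gngt2 2.65-fold [2.18 to 3.24] higher. Dapl1, the T cell gene Cd8b1 and the mature dendritic cell gene Fscn1 were 22.9-fold [7.55 to 113], 9.98-fold [4.35 to 28.1] and 8.07-fold [3.48 to 22.9] lower, each seen in at most 8 control cells, and Fscn1 had a log2 ratio of 1.05 with the stricter filter. Lists of other cell types lay below the random lists in the same cells, at -1.70 for cytotoxic, -1.22 for naive T cell and -1.01 for B cell isotype genes. In type 1 conventional dendritic cells interferon genes had 8 of 12 higher and a median of 0.49 against -0.25 to 0.18, a call lost at a minimum of 1 count (-0.00895) and at a minimum of 100 counts (-0.032). Ifi27l2a was at -0.032 [-0.19 to 0.13], Ifitm3 at 0.60 [0.41 to 0.80] and Bst2 at 0.60 [0.38 to 0.82]. Mfge8, an adaptor for uptake of dying cells, and Fdps of the sterol pathway were 4.68-fold [2.25 to 10.9] and 2.81-fold [2.22 to 3.59] higher there, with AY036118 2.21-fold [2.002 to 2.43] higher, and the metallothionein gene Mt2, Cd5 and Fbxo33 were 2.14-fold [1.90 to 2.41], 3.53-fold [1.87 to 7.14] and 2.29-fold [1.69 to 3.13] lower. Inside the random range lay inflammatory 0.10 (9 of 15 higher, Il1b 0.10, Cxcl1 -1.85; outside with doublets kept at 0.22 and with the stricter filter at 0.16), MHC class II 0.081 (9 of 13 higher, Cd74 0.14, Cd40 -0.63) and immediate early 0.088 (13 of 18 higher, Junb 0.11, Hspa1b 0.54) genes.

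Exposed T and B cells also had higher interferon transcripts. In T cells 14 of 18 were higher (median 0.47 against -0.26 to 0.063). Ifi27l2a was at 0.31 [0.24 to 0.37], Cxcl10 at 1.16 [0.82 to 1.51] and Isg15 at 0.72 [0.54 to 0.92]. Genes of type 2 lymphocytes had 7 of 9 lower and a median of -0.46 against -0.38 to 0.18, a call lost with each cell weighing the same (-0.34) and with doublets kept (-0.30). Gata3 (the main transcription factor of type 2 cells) was at -0.72 [-0.88 to -0.56], Areg (an epidermal growth factor family gene) at 0.47 [0.084 to 0.87] and Il1rl1 at -1.29 [-1.95 to -0.68]. Activation genes had 8 of 10 lower and a median of -0.25 against -0.25 to 0.069, a call lost with 5 counts added (-0.25), with each cell weighing the same (-0.20) and with doublets kept (-0.20). Cd69 was at -0.44 [-0.53 to -0.36], Icos at -0.15 [-0.25 to -0.057], Tnfrsf9 at -1.33 [-2.02 to -0.69] and Ctla4 at -0.57 [-0.74 to -0.41]. A cluster led by Ctla4, Tnfrsf4, Ikzf2 and Foxp3, genes of regulatory T cells, held 148 control and 98 exposed cells. Inside the random range lay type 1 and type 17 -0.11 (3 of 7 higher, Ifng -0.16, Ccr6 0.29), immediate early -0.029 (7 of 18 higher, Junb -0.013, Ier3 1.87), cytotoxic -0.16 (4 of 11 higher, Ccl5 -0.069, Gzmb 0.72; outside with each cell weighing the same at -0.30 and with the stricter filter at -0.30) and naive T cell -0.12 (1 of 8 higher, Klf2 -0.075, Ccr7 -0.26) genes. Elovl6, a fatty acid elongase, was 2.73-fold [2.21 to 3.39] higher, with Gm26870 3.67-fold [2.32 to 6.005] and Hspa1b 1.89-fold [1.75 to 2.04] higher and Gm29562, Mir142hg and Mogat1 4.62-fold [2.55 to 8.96], 2.34-fold [1.84 to 2.998] and 2.94-fold [1.68 to 5.36] lower. In B cells 12 of 15 interferon genes were higher (median 0.29 against -0.31 to 0.083). Some had few UMIs (Isg15 46 control, 72 exposed). Ifi27l2a was at 0.29 [0.22 to 0.35]. Immediate early genes had 13 of 18 higher and a median of 0.19 against -0.21 to 0.065. Jund was at 0.23 [0.19 to 0.26], Junb at 0.067 [0.030 to 0.10], Jun at 0.55 [0.49 to 0.62] and Egr1 at 0.52 [0.43 to 0.61]. Isotype and activation genes had 10 of 11 lower and a median of -0.25 against -0.24 to 0.098, a call lost at a minimum of 1 count (-0.21), at a minimum of 100 counts (-0.21), with doublets kept (-0.17) and with the stricter filter (-0.15). Ighm was at -0.28 [-0.30 to -0.26], Igha at -0.45 [-0.49 to -0.42], Ighg3 at -5.74 [-6.36 to -5.23] (92.5% of the UMIs of the higher library in 1 cell) and Ighg2c with 0 exposed and 24 control UMIs. A cluster led by Iglc1, Igkc, Iglc2 and Ighm held 594 control and 406 exposed cells, and the most one-sided B cell sub-cluster 490 and 166. MHC class II lay inside the range at 0.053 (8 of 13 higher, Cd74 0.20, Cd80 -1.13; outside with doublets kept at 0.11). Ly6a, an interferon-inducible surface protein, was 1.70-fold [1.59 to 1.81] higher, with Gm26510 2.44-fold [1.57 to 3.86] and Gm10076 1.69-fold [1.54 to 1.85] higher, and Tnfrsf17, the plasma cell receptor BCMA, 3.70-fold [2.34 to 6.08] lower, seen in 8 control and 4 exposed cells, with Ly6k 3.85-fold [2.11 to 7.51] and Fam46c 2.71-fold [2.04 to 3.64] lower.

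NK cells had higher cytotoxic transcripts, with 10 of 11 members higher and a median of 0.20 against -0.15 to 0.11. Ccl5 was at 0.22 [0.20 to 0.24] and Gzma (a granzyme gene) at 0.23 [0.20 to 0.25]. Their interferon 0.089 (9 of 14 higher, Ifi27l2a 1.05) and immediate early -0.077 (7 of 18 higher, Junb 0.00595, Hspa1a 1.37) genes lay inside the random range. Hspa1a, Tmem108 and AY036118 were 2.58-fold [2.12 to 3.16], 4.02-fold [2.09 to 8.37] and 2.18-fold [1.94 to 2.45] higher, and the cytokine gene Csf2, the trypsinogen gene Prss2 and 0610010F05Rik 5.38-fold [2.73 to 11.8], 3.83-fold [1.89 to 8.55] and 2.69-fold [1.57 to 4.79] lower. With the stricter filter the Csf2 and Prss2 log2 ratios were -0.80 and -0.40. Group 2 innate lymphoid cells, the early source of interleukin 5 and interleukin 13, had 8 of 8 cell cycle genes higher and a median of 1.64 against -0.28 to 0.28. Hmgb2 was at 0.33 [0.12 to 0.55], Tubb5 at 0.36 [0.10 to 0.63], Mki67 with 49 exposed and 0 control UMIs (71.4% of the UMIs of the higher library in 1 cell) and Top2a at 4.92 [2.93 to 10.82] (58.7% of the UMIs of the higher library in 1 cell). The median was 0.62 with each cell weighing the same. This rested on few cells, since Stmn1 (12.5-fold [6.76 to 25.6] higher) had UMIs in 6 control and 9 exposed cells. Interferon genes had 5 of 6 higher and a median of 0.55 against -0.43 to 0.42, a call lost with each cell weighing the same (0.36), with the added free-RNA subtraction (0.33), with doublets kept (-0.54) and with the stricter filter (-0.29). Bst2 was at 0.41 [-0.24 to 1.09], Ifitm3 at 2.67 [1.76 to 3.85] (80.9% of the UMIs of the higher library in 1 cell) and Ifi27l2a at 1.37 [0.20 to 2.80]. Immediate early genes had 11 of 18 higher and a median of 0.18 against -0.12 to 0.14, a call lost with doublets kept (-0.064). Junb was at 0.27 [0.20 to 0.35], Zfp36 at -0.37 [-0.48 to -0.25], Hspa1b at 1.79 [1.27 to 2.37] and Atf3 at -0.997 [-1.47 to -0.55]. Hspa1b and AY036118 were 3.50-fold [2.41 to 5.18] and 2.94-fold [2.37 to 3.66] higher. Type 2 lymphocyte genes lay inside the range at -0.16 (4 of 10 higher, Gata3 -0.29, Areg 0.80).

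Over the 11 classes compared, 176 pairs of a list and a class gave a median, the ribosomal and mitochondrial lists kept as checks not counted, and 72 of them lay outside the central 95% of random lists, 20 above and 52 below. The 78 pairs described here were picked after all medians had been seen, and 39 of them lay outside, 17 above and 22 below. Of the 98 pairs not described 33 lay outside, 3 above and 30 below. Members of a list are not independent of each other, so these counts are not counts of tests passed. Of the 22 pairs of the ribosomal and mitochondrial lists 9 lay outside, 4 above and 5 below. The aryl hydrocarbon receptor list, which holds Cyp1a1 and other genes that respond to polycyclic aromatic compounds, had fewer than 5 counted members in each class compared and gave no median.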

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

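The rule for lists that moved in opposite directions ran on the 78 pairs picked after the medians were seen, and the tests below were chosen after the results were seen, except those of depth, of the number of libraries, of heart muscle RNA and of body cavity macrophages. None of the differences between classes in the next paragraph was tested, since each class has 1 library per group.

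Interferon genes lay above the random lists in neutrophils (0.68) and below them in alveolar macrophages (-0.63), medians that differed by 1.31, but the second was inside its range or turned with doublets kept (0.42), with the stricter filter (-0.10) and without the mixed cluster (-0.15). The MHC class II medians of type 2 dendritic cells (0.18) and alveolar macrophages (-1.02) differed by 1.20, the second at -0.44 without the mixed cluster and -0.51 with doublets kept. Cell cycle medians of group 2 innate lymphoid cells (1.64) and interstitial macrophages (-0.80) differed by 2.44. The second turned direction at a minimum of 100 counts (0.029), with each cell weighing the same (0.34) and without the highest cells (0.11), and the first was 0.62 with each cell weighing the same, so the opposite directions depended on the processing. Inflammatory medians of classical monocytes (0.31) and interstitial macrophages (-0.22) differed by 0.53, the first at -0.15 without the sub-clusters chosen by library and the second inside its range at a minimum of 100 counts (-0.089). Maturation medians of interstitial macrophages (0.24) and classical monocytes (-0.47) differed by 0.71. The first was inside its range without the highest cells (0.10), with doublets kept (0.13) and with the stricter filter (0.056), and the second without the highest cells (-0.22), with doublets kept (-0.27) and with the stricter filter (-0.27). Immediate early medians of B cells (0.19) and classical monocytes (-0.21) differed by 0.40, the second at 0.35 without the sub-clusters chosen by library.

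The genes higher in exposed classical monocytes, led by Lrg1 and Saa3, were weighed against 3 technical explanations. Average neutrophil RNA could not bring the 10 named genes as a sum, which would need 163% neutrophil RNA. S100a8, S100a9 and Retnlg gained 0.00254 of that need. Single genes and kinds of neutrophil were not tested. Shares of cells lay apart after thinning for 6 of 7 genes, F11r being the exception. Those genes were picked for large CPM ratios, which already allow for depth, so this result says little on depth. A few extreme cells were argued against, with 0 of 10 genes having most of their UMIs in 1 cell. With 1 library per group the exposure cannot be told apart from infection, genotype or CD45 labels, preparation day or any other difference. An effect of the exposure on monocytes stays open as an untested hypothesis.

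Lower MHC class II and interferon genes in exposed alveolar macrophages may come in part from cells joined to other cell types in 1 cluster, which held more control (46) than exposed (22) cells at medians of 27937.5 and 28000.5 UMIs. Without it the MHC class II median moved from -1.02 to -0.44 and the interferon median from -0.63 to -0.15, and the MHC class II median still lay below the range of random lists of all alveolar macrophages (-0.15 to 0.095). TMM (MHC class II at -0.96) shifts all genes alike and cannot test scaling. Lists of B cell isotype (-0.96), cytotoxic (-0.73) and naive T cell genes (-1.76) were lower there too, but B cell RNA was argued against as the whole source of the MHC class II difference, since Igkc, Ighm and Ighd together differed by 0.0380 of what it would need. What remains of the MHC class II difference cannot be assigned to the exposure with 1 library per group.

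The genes named as lower in exposed interstitial macrophages may come from a few control cells, since for 10 of the 10 genes at most 5 cells held 90% of the control UMIs. For Serpinb2, Prg4, Saa3 and Alox15 the pattern depended on doublet removal and filter, with log2 ratios of -2.38, -1.53, -0.58 and -0.37 with doublets kept and -2.60, -2.19, -0.72 and -0.92 with the stricter filter. Heart muscle RNA in 1 cell is a candidate source of Myl7, Myl4, Actc1, Sln and Mb: 5 of 6 other heart muscle genes had a UMI in it, led by Tnni3 with 133 and Tnnt2 with 74 of 20519 UMIs but with 0 for Nppa, though the CD45 sort should remove muscle cells. Body cavity macrophages, which carry CD45, are a candidate source of those 4 genes in the control cells kept: 6 of 7 of their other marker genes were at least 5 times higher in the 3 cells with at least 3 Serpinb2 UMIs, led by F5 at 1078 against 3.33 CPM and Ltbp1 at 855 against 0.665 CPM, while Gata6 had 0 UMIs. No biological explanation by the exposure was tested for this pattern.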

How the results depend on the processing

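List medians, share ratios and Ccr2 percentages are given where they moved beyond their counting interval or turned direction, and log2 ratios of single genes where they turned direction. Genes named by size are also given, here or with the main results, where they moved beyond their interval and by over 2-fold, except with 5 counts added, which moves genes near 0 counts alone, and without the monocyte sub-clusters, which were chosen by library. The settings that leave out cells (1 cell per gene, 1 cluster or monocyte sub-clusters) and the free-RNA subtraction by neutrophil genes (by B cell genes in neutrophils) were chosen after the results were seen. The cause of the moves was not tested. Scaling factors shift every list of a class and its random lists alike, so medians under other scalings were not set against the range of random lists. With 1 library per group (replicate 1 in each) no library was left out in turn, since none would remain in its group. No paired analysis was possible because the labels name no animal or batch shared by the 2 libraries.

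Of the 78 medians, 78 stayed within their intervals with 5 counts added, 72 without 4 gene kinds, 72 with a minimum of 1 count, 72 without the highest cells, 63 with each cell weighing the same, 61 with the stricter filter, 55 with TMM and 55 with median-of-ratios factors. With doublets kept 55 of 77 stayed, with a minimum of 100 counts 67 of 73 and with the added free-RNA subtraction 64 of 68. Of the 140 log2 ratios of named genes 39 moved and 2 turned with doublets kept, 28 and 3 with the stricter filter, 26 and 3 without the highest cells and 26 and 1 with each cell weighing the same, and of 32 in classical monocytes 26 and 2 without the sub-clusters chosen by library. All 16 share ratios stayed within their intervals at Leiden resolutions 0.6 and 1.6. TMM shifted every log2 ratio by 0.14 in B cells, 0.11 in T cells and 0.11 in neutrophils, and median-of-ratios by 0.12, 0.11 and 0.094 there and by 0.11 in type 2 dendritic cells. The planned free-RNA subtraction by haemoglobin and epithelial genes gave values in neutrophils and NK cells alone, on 66 and 13 control and only 5 and 1 exposed UMIs of those genes, and all 10 medians there stayed within their intervals. In the other 9 classes the estimate exceeded 20% in at least 1 library, from 26.8% in exposed classical monocytes to 1980.1% in exposed group 2 innate lymphoid cells, so it gave no value there. The added subtraction by neutrophil genes gave none in nonclassical monocytes, where the estimate was 119.963% and 103.052%, which leaves 10 lists without a value. A minimum of 100 counts left no value for 5 lists (cell cycle in 3 classes, type 1 and type 17 in T cells, interferon in group 2 innate lymphoid cells), and the compartment denominator none for proliferating cells. No value could be had for basophils with the stricter filter, plasmacytoid cells with no filter, basophils, plasmacytoid and gamma-delta T cells with each library clustered alone, or the type 1 and type 17 list in T cells with doublets kept.

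TMM factors gave in classical monocytes -0.32 for interferon, 0.22 for lysosome and -0.13 for immediate early, and in alveolar macrophages 0.028 for NRF2, 0.11 for lysosome, 0.13 for lipid handling and 0.075 for immediate early. For neutrophils the values were 0.083 for NRF2, 0.13 for inflammatory, 0.79 for interferon, 0.35 for granules and 0.15 for glycolysis, and in nonclassical monocytes 0.073 for MHC class II. For type 2 dendritic cells the values were 0.27 for MHC class II and -0.10 for immediate early, and in B cells 0.19 for MHC class II, 0.33 for immediate early and -0.11 for isotypes. For T cells the values were 0.58 for interferon, 0.077 for immediate early, -0.15 for activation and -0.011 for naive T cell, and in NK cells 0.24 for cytotoxic. Median-of-ratios factors gave in classical monocytes -0.37 for chemokines, 0.30 for NRF2, -0.30 for interferon, 0.23 for lysosome and -0.12 for immediate early, and in alveolar macrophages 0.088 for lysosome and 0.11 for lipid handling. For neutrophils the values were 0.066 for NRF2, 0.11 for inflammatory, 0.77 for interferon, 0.33 for granules and 0.13 for glycolysis, and in nonclassical monocytes 0.067 for MHC class II. For type 2 dendritic cells the values were 0.28 for MHC class II and -0.090 for immediate early, and in B cells 0.17 for MHC class II, 0.31 for immediate early and -0.13 for isotypes. For T cells the values were 0.58 for interferon, 0.080 for immediate early, -0.14 for activation and -0.00703 for naive T cell, and in NK cells 0.22 for cytotoxic. CPM without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes gave in type 1 dendritic cells 0.036 for MHC class II and 0.042 for immediate early, and in B cells 0.11 for MHC class II and 0.25 for immediate early, and in T cells 0.033 for immediate early and -0.054 for naive T cell.

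The mean of per-cell CPM gave in classical monocytes -0.36 for chemokines, -0.18 for interferon, -0.14 for immediate early and 0.25 for glycolysis, and in alveolar macrophages -0.66 for MHC class II and -0.049 for immediate early. For interstitial macrophages the values were -0.37 for inflammatory, 0.056 for MHC class II, 0.34 for cell cycle, -0.20 for immediate early, -3.57 for Myl7 and -4.05 for Myl4, and in neutrophils -0.26 for Chil3. For nonclassical monocytes the values were -0.12 for chemokines, and in B cells 0.11 for immediate early and -0.31 for isotypes, and in T cells -0.30 for cytotoxic, and in innate lymphoid cells 0.62 for cell cycle. A minimum of 1 count gave in classical monocytes -0.099 for chemokines, and in alveolar macrophages -0.35 for interferon, and in interstitial macrophages -0.18 for chemokines, and in neutrophils 0.18 for granules, and in nonclassical monocytes -0.11 for cell cycle, and in type 1 dendritic cells -0.00895 for interferon. A minimum of 100 counts gave in classical monocytes -0.20 for alternative activation, and in interstitial macrophages -0.089 for inflammatory, -0.26 for interferon and 0.029 for cell cycle, and in neutrophils -0.023 for NRF2, and in type 1 dendritic cells -0.032 for interferon. The added free-RNA subtraction gave in classical monocytes -4.73 for alternative activation, -0.17 for lipid handling, -1.04 for maturation, -2.25 for S100a9 and -11.55 for Retnla. S100a9 was among the genes that set its size there, so the S100a9 value is no check of that gene. Neutrophils had -0.083 for chemokines, -0.00642 for S100a8 and -0.14 for Chil3. The planned free-RNA subtraction gave in neutrophils -0.054 for Chil3.

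Keeping doublets gave in classical monocytes -0.32 for chemokines, -0.53 for MHC class II and -0.16 for S100a9. For alveolar macrophages the values were -0.098 for chemokines, 0.043 for inflammatory, 0.42 for interferon, -0.51 for MHC class II, 0.034 for lipid handling, 0.79 for Ccr2, -4.22 for Retnla and -1.29 for Cd209a. Interstitial macrophages had 0.17 for NRF2, -0.098 for MHC class II and 0.39 for lipid handling. For nonclassical monocytes the values were 0.32 for inflammatory, 0.13 for interferon, -0.23 for MHC class II, 0.013 for lysosome, -0.37 for lipid handling, 0.18 for glycolysis and -2.82 for Lyz1. For type 1 dendritic cells the values were 0.22 for inflammatory, 0.67 for interferon and 0.040 for MHC class II, and in B cells 0.11 for MHC class II, and in innate lymphoid cells -0.54 for interferon and -0.064 for immediate early. T cells had 0.16 for Ccr2. Share ratios there were 1.08 in nonclassical monocytes and 0.942 in proliferating cells. The stricter filter (1000 UMIs, 500 genes, 5% mitochondrial) gave in classical monocytes -5.86 for Retnla, and in alveolar macrophages -0.10 for interferon, -0.81 for alternative activation, 0.094 for lysosome, 0.10 for lipid handling and 0.041 for Ccr2. For interstitial macrophages the values were 0.25 for MHC class II, -0.54 for alternative activation, -0.24 for lipid handling and 0.056 for maturation, and in nonclassical monocytes 0.010 for interferon and -0.18 for MHC class II. For type 1 dendritic cells the values were 0.16 for inflammatory and 0.052 for immediate early, and in type 2 dendritic cells 0.49 for interferon and 1.05 for Fscn1, and in B cells 0.11 for immediate early, and in T cells -0.30 for cytotoxic and -0.064 for naive T cell. Innate lymphoid cells had -0.29 for interferon and 0.12 for Ccr2. Share ratios there were 1.16 in B cells and 0.923 in neutrophils. No cell filter gave share ratios of 1.12 in basophils, 0.603 in mature dendritic cells and 0.471 in proliferating cells. The myeloid or lymphoid compartment as denominator gave 0.927 in neutrophils. Clustering each library alone gave 1.15 in T cells.

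Leaving out all monocyte sub-clusters with at least 90% of cells from 1 library gave in classical monocytes -0.16 for chemokines, -0.25 for NRF2, -0.15 for inflammatory, -0.00545 for interferon, -0.63 for MHC class II, 0.00584 for lysosome, 0.35 for immediate early and 0.14 for glycolysis. S100a8 was at -0.62 and S100a9 at -0.19. The share ratio was 0.719 there. Leaving out the most one-sided monocyte sub-cluster gave in classical monocytes -0.27 for chemokines, 0.14 for NRF2, -0.24 for interferon, 0.00611 for MHC class II, -0.35 for cell cycle, -0.00464 for immediate early, 0.24 for glycolysis and -0.062 for S100a9. The share ratio was 1.14 there. Leaving out the mixed alveolar macrophage cluster gave in alveolar macrophages -0.066 for chemokines, -0.15 for interferon, -0.44 for MHC class II, 0.037 for lipid handling and 0.29 for Ccr2. Leaving out the nonclassical cluster with neutrophil transcripts gave in nonclassical monocytes 0.29 for NRF2, 0.25 for inflammatory, 0.084 for MHC class II and 1.56 for Il1r2. Leaving out the highest cell of each gene gave in classical monocytes -0.29 for chemokines, -0.22 for maturation, 6.46 for Saa3 and -5.89 for Retnla, and in alveolar macrophages -0.55 for alternative activation and -3.60 for Cd209a. For interstitial macrophages the values were -0.38 for inflammatory, 0.11 for cell cycle, -0.20 for Hmox1, 2.06 for Myl4, 0.48 for Mb, -1.11 for Actc1 and -1.11 for Sln. For type 2 dendritic cells the values were -6.04 for Cd8b1 and -1.76 for Fscn1, and in T cells -0.19 for cytotoxic. Thinning gave Ccr2 UMIs in 41.0% of control and 49.1% of exposed cells. All kept cells gave 18.5% and 20.3%.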

Other observations

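The values in this part were picked after the results had been seen, except the test of clustering without the named genes, whose outcome was predicted first.

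A pair of transcripts differed between the libraries in the same direction in all 11 classes compared. AY036118, a long noncoding transcript (ENSMUSG00000105361 on chromosome 17 from 39847113 to 39848035), was higher in the exposed library in each, from a log2 ratio of 0.34 in T cells to 1.74 in interstitial macrophages. Igkc, the immunoglobulin kappa constant gene that B cells express, was lower in each, from -0.14 in B cells to -3.81 in type 2 dendritic cells. The B cell value depended on scaling and on single cells, at -0.00196 with TMM, -0.023 with median-of-ratios factors and -0.46 without the highest cell of each library. In neutrophils Igkc was at 24.2 against 104 CPM and in NK cells at 14.8 against 61.6 CPM, levels that in cells other than B cells are read as background. The cause of either difference was not tested.

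Among the pairs of lists and classes not described above, most that lay outside the random lists concerned genes of another cell type and were lower in the exposed library. Naive T cell genes had medians of -1.63 in classical monocytes, -1.76 in alveolar macrophages, -1.66 in interstitial macrophages, -1.53 in neutrophils, -0.94 in nonclassical monocytes, -0.86 in type 1 dendritic cells, -1.22 in type 2 dendritic cells and -0.24 in NK cells. B cell isotype genes had -0.41 in classical monocytes, -0.96 in alveolar macrophages, -1.16 in neutrophils, -0.73 in nonclassical monocytes, -0.43 in type 1 dendritic cells, -1.01 in type 2 dendritic cells, -0.44 in T cells and -0.49 in NK cells. Cytotoxic genes had -0.73 in alveolar macrophages, -0.69 in neutrophils, 0.67 in nonclassical monocytes, -2.95 in type 1 dendritic cells, -1.70 in type 2 dendritic cells and -0.66 in B cells, with 6 of 6 higher in nonclassical monocytes. MHC class II genes had -0.52 in neutrophils, 0.10 in T cells, -0.44 in NK cells and -1.56 in group 2 innate lymphoid cells. The others were T cell activation (-0.52 in type 1 dendritic cells and -0.38 in NK cells), cell cycle (-0.77 in neutrophils and -0.33 in T cells), lipid handling (-0.53 in type 2 dendritic cells), neutrophil granules (-0.39 in alveolar macrophages) and inflammatory genes (0.43 in group 2 innate lymphoid cells). As checks, ribosomal protein genes had -0.24 in neutrophils, 0.16 in nonclassical monocytes, -0.077 in type 1 dendritic cells, -0.052 in type 2 dendritic cells, 0.21 in B cells, 0.15 in T cells and 0.064 in NK cells, and mitochondrial transcripts -0.23 in B cells and -0.18 in group 2 innate lymphoid cells.

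The hypothesis that classical monocytes of the exposed library fall into different kinds was tested by clustering the monocytes again without the 20 named genes. The most one-sided sub-cluster then had 98.8% of its cells from the exposed library (166 of 168), and 167 of its cells were shared with the 173 found with the genes included, so the split may reflect a broad programme and not those genes alone. Sub-clusters with at least 90% of their cells from the exposed library held 334 to 344 cells at 5 resolutions from 0.2 to 1.6, of which 4 to 7 were control cells. At resolution 1 those cells had Wfdc21 at 173 CPM and S100a8 at 810.3 CPM, against 8.77 and 67.0 CPM in the other exposed and 3.31 and 103 CPM in the other control monocytes. Ly6c2 was lower in them (817 CPM against 1311 and 1665 CPM), and H2-Ab1 was 828 CPM against 393 and 805 CPM. The split was not complete, since the other exposed monocytes also had more Lrg1, Saa3 (120.4 against 16.3 CPM) and Prtn3 (27.5 against 6.33 CPM) than those of the control library. Without batch correction and with 1 library per group, a difference between libraries in all monocytes would give such a split too.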
